A study of Mus musculus and Homo sapiens with 65 samples.

How the data were processed

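The series holds 65 samples, of which 9 RNA-seq libraries of mouse late 2-cell embryos were analysed. They fall into 4 groups by their labels: 3 wild-type libraries, 2 from embryos treated with alpha-amanitin, 2 from embryos injected with mismatch control morpholinos, and 2 from embryos injected with morpholinos against Kdm5a and Kdm5b. ChIP-seq, bisulfite sequencing and the RNA-seq libraries made from small numbers of cells were not analysed here.

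Per the labels' protocols, zygotes were injected at 0.5 days after conception, embryos were cultured to the late 2-cell stage, RNA was extracted with a QIAGEN RNeasy Micro kit, and libraries were made by the TruSeq procedure. Per the submitters' processing notes, which give no roles or order, the tools used across the series were BWA, Picard, Cufflinks, Trimmomatic, Bismark (version 12.5) and SAMtools, and the genome build of these libraries was mm10. The aligner of the RNA-seq reads, its settings and the annotation release are not given in the sources used here. The authors deposited, per the file headers, 1 table per library in the layout of Cufflinks, with the FPKM (fragments scaled by transcript length and by the library's mapped fragments) of 32287 genes, a lower and an upper bound of each FPKM, and a quantification status. FPKM divides by the library's own total, so every level is relative to the other transcripts of the same library, and the files hold no rows of spiked-in RNA.

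Read counts are not part of these files, so depth in reads is unknown. The bounds of the FPKM gave a relative measure. It was taken over 7491 genes with status OK, a lower bound above 0 and an FPKM inside its bounds in all 9 libraries. Between 282 and 945 genes per library had an FPKM above its own upper bound. There were 945 and 707 in the mismatch controls and 852 and 741 with the Kdm5a+b morpholinos, so the bounds do not hold for every gene. The median width from the lower to the upper bound, divided by 2, was 18.7% to 19.4% of the FPKM in wild-type libraries and 21.5% and 24.4% in alpha-amanitin libraries. It was 11.9% and 14.8% in mismatch control libraries, and 13.0% and 14.3% in Kdm5a+b morpholino libraries. From the same bounds, with wild-type replicate 1 set to 1, the relative depth was 0.87 and 0.88 in the other wild-type libraries, 1.22 and 0.92 with alpha-amanitin, 2.26 and 1.59 in the mismatch controls, and 1.96 and 1.60 with the Kdm5a+b morpholinos. These bounds cover the counting and assignment of fragments only. A status of FAIL stood at 15 genes in 1 or more of 7 libraries, always with an FPKM of 0, so such a 0 is a failed estimate. Of common housekeeping genes, Actb lay between 16.1 and 77.5 FPKM and Eef1a1 between 14.4 and 65.4 FPKM, while Gapdh lay between 0 and 1.74 FPKM and was listed at 0 in wild-type replicate 2. A 0 is therefore described as "listed at 0", with each library's value and no fold.

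Gene IDs, symbols and positions are those of the files, and positions were written counting from 1. Of the 32287 gene IDs, 31670 (98.1%) were found in GENCODE release M21 of the mouse build GRCm38, which is mm10, and 24993 of these had the same start. That annotation gave the gene biotypes and the exons around the morpholino sites, which were located by exact match of the reverse complement in the sequence of the target gene's chromosome.

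Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), on 13137 genes with an FPKM of 1 or more in at least 2 of the 9 libraries. A linear model with group as the only term was fitted to all 9 libraries, which share 1 estimate of the spread with 5 residual degrees of freedom, followed by eBayes with a trend on the mean level. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 changes are differences in log2(FPKM + 1) with standard errors (SE) from that model; they understate the change of genes at low FPKM. Means ± SD are of FPKM. The labels do not say whether replicates came from separate collections of embryos, so the p-values measure the spread between these libraries, which may be partly technical. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333, so calls rest on the model.

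Gene lists were fixed before the data were examined: 22 lists of genes for pathways, complexes and stages that bear on zygotic transcription, plus markers of cumulus, sperm, blood and oviduct cells that an embryo collection could carry. The list of mitochondrially encoded transcripts and the list of ribosomal and other RNAs made by RNA polymerases I and III held no gene of the files. The 20 lists with at least 3 tested members were tested with camera in limma, with its preset correlation of 0.01 between genes and adjustment over the 20 lists. The test asks whether a list's genes moved relative to all other tested genes. The estimated correlation and fry were alternatives; fry tests whether a list's genes moved, on balance, one way, and does not compare them with other genes. In each comparison the genes named were taken, by a rule also fixed then, from the 8 largest rises and 8 largest falls among called genes whose libraries do not overlap between the groups and whose mean FPKM is 5 or more in the higher group, without predicted genes and clones; up to 3 members of each list with the smallest p; and Kdm5a and Kdm5b. Zfp352, Rps9 and Zbed3 were carried over from the alpha-amanitin comparison to the others after their values were seen. Other genes are said to have been chosen after their values were seen. Some genes that the rule names are not reported here.

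The procedure was tested on simulated data with the same group sizes and 200 changed genes in each of 5 runs. The changed genes were drawn from those with a mean level above 5 FPKM in wild type, and noise was independent between genes. Recovery at lower levels was not measured. For Kdm5a+b morpholino against mismatch control (12311 genes on average) it recovered 1.79% of 2-fold, 36.4% of 4-fold and 66.4% of 8-fold changes, with 2.8 false calls per run. For alpha-amanitin against wild type (12306 genes) the shares were 4.18%, 46.6% and 78.5%, and for mismatch control against wild type (12302 genes) 2.39%, 45.1% and 74.8%. In the data, alpha-amanitin changed 3865 genes and not 200, which loosens the Benjamini-Hochberg cutoff. The simulated shares therefore do not describe that comparison. Each of the other comparisons called no gene, so the cutoff is stricter there than with 200 changed genes. Their simulated shares may be too high.

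Alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of 5 or more, median-of-ratios scaling, rescaling to TPM (FPKM divided by its sum in the library), quantile normalization, only the libraries of the 2 groups compared, the replicate number as a block in 2 codings, eBayes without the trend, array quality weights, a 2-fold minimum, rows summed by symbol, genes with a status other than OK set aside, and leaving out each library in turn. Kdm5a+b morpholino libraries were also set against wild-type libraries, and against wild-type and mismatch control libraries together. Protein-coding genes alone, and the genes that rose under alpha-amanitin as a set, were chosen after seeing the data.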

Results

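RNA-seq was performed on late 2-cell mouse embryos, the stage at which the embryo's own genome is first broadly transcribed while RNA stored in the egg is being cleared. There were 3 wild-type libraries, 2 libraries from embryos treated with alpha-amanitin, a mushroom toxin that blocks RNA polymerase II, 2 from embryos injected with morpholinos against Kdm5a and Kdm5b, and 2 from embryos injected with mismatch control morpholinos. KDM5A and KDM5B are enzymes that remove methyl groups from lysine 4 of histone H3. Morpholinos are antisense oligomers that block translation or splicing of their target. The number of genes at an FPKM of 1 or more was 10611 to 11228 in the wild-type, control and Kdm5a+b libraries, and 7977 and 7935 with alpha-amanitin. Log2 levels of wild-type replicates correlated across the tested genes at r = 0.846 to 0.862, those of the 2 alpha-amanitin libraries at 0.876, of the mismatch controls at 0.888 and of the Kdm5a+b libraries at 0.902. Alpha-amanitin libraries correlated with all others at 0.61 to 0.689 only. Read counts are not in the files, so depth in reads is unknown. These correlations are across genes, which are not independent replicates.

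The targeted genes come first. Kdm5a (ENSMUSG00000030180.10, mm10 chromosome 6, 120364099 to 120444574) stood at 11.1 ± 2.38 FPKM in the mismatch controls and at 17.4 ± 2.91 FPKM in the Kdm5a+b morpholino group (SD, n = 2 each). Its level was 12.8 and 9.44 FPKM in the control libraries and 19.5 and 15.3 FPKM in the Kdm5a+b libraries, beside 14 ± 2.97 FPKM (SD, n = 3) in wild type. Kdm5b (ENSMUSG00000042207.12, mm10 chromosome 1, 134560171 to 134635285) stood at 47.4 ± 11.1 FPKM in the controls, at 32.8 ± 7.40 FPKM in the Kdm5a+b group (SD, n = 2 each) and at 51.5 ± 15.6 FPKM (SD, n = 3) in wild type. The log2 differences of Kdm5a+b from control embryos were 0.61 (SE 0.42) for Kdm5a and -0.52 (SE 0.53) for Kdm5b. Neither passed limma's test (adjusted p = 1 for both), and the exact permutation p was 0.333 for each, the smallest that 2 against 2 libraries allow. The Kdm5a morpholino, TGACGGCCACCAAAGCCCTCTCA, matches the transcript at chromosome 6, 120364526 to 120364548, in the 5′ untranslated part of an exon ahead of the start codon at 120364614 to 120364616. The Kdm5b morpholino, AGCACAGGGCAGGCTCCGCAACC, matches at chromosome 1, 134560294 to 134560316, also in the 5′ untranslated region, ahead of the start codon at 134560339 to 134560341. Each site occurs 1 time in its gene. A morpholino in that place can block translation and leave the mRNA in place, so these levels do not check the labels, and protein levels were not analysed here.

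Alpha-amanitin against wild type asks which transcripts of the late 2-cell embryo need new transcription. How alpha-amanitin was given, and its dose, are not given in the sources used here, so any effect of handling or vehicle cannot be separated from it. Genes known to switch on at the 2-cell stage fell. Zfp352, a zinc finger gene of this stage, fell from 90.2 ± 10.2 FPKM (SD, n = 3) to 2.41 ± 0.908 FPKM (SD, n = 2), 37.4-fold, and Tdpoz1 fell from 40.6 ± 9.85 to 0.151 ± 0.0426 FPKM. Ubtfl1 stood at 36.0, 55.0 and 42.3 FPKM in wild type and was listed at 0 in both alpha-amanitin libraries. Genes of protein synthesis were among those that fell, including Rps9, which encodes a protein of the small ribosomal subunit and stood at 96.9, 142 and 129 FPKM in wild type against 0.836 and 0. Of 13137 genes tested, 3299 were lower and 566 higher with alpha-amanitin (limma, adjusted p under 0.05).

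The largest falls by the naming rule were of genes of varied function. Vimp, a selenoprotein of the endoplasmic reticulum, fell from 1100 ± 655 to 0.368 ± 0.483 FPKM. Slc34a2, a sodium-dependent phosphate transporter, fell from 238 ± 23.3 to 0.407 ± 0.487 FPKM (adjusted p = 1.69e-07), and the protein kinase Hipk1 fell from 169 ± 21.9 to 0.728 ± 0.0682 FPKM (adjusted p = 1.69e-07; SD, n = 3 and 2). Rab1, a GTPase of vesicle transport, stood at 59.0, 86.3 and 67.8 FPKM in wild type against 0.0761 and 0, and the homeobox gene Crxos at 51.1, 92.3 and 52.3 FPKM against 0.257 and 0. The pseudogenes Cd63-ps and Rps26-ps1 are also among the 8 largest falls; reads of such copies may be shared with their parent genes. Of 4453 genes with a wild-type mean of 10 FPKM or more, 488 (11%) were under 1 FPKM in both alpha-amanitin libraries. Both targeted genes fell: Kdm5b changed by -4.16 on the log2 scale (SE 0.49, adjusted p = 0.000119), to 0.575 and 4.16 FPKM (-3.30 without alpha-amanitin replicate 1 and -5.01 without replicate 2), and Kdm5a by -3.74 (SE 0.38, adjusted p = 4.95e-05), to 0.228 and 0 FPKM.

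Of the 39 tested members of the 2-cell specific list, 33 fell, none rose and 6 did not pass (36 fell adjusted over the list alone); the median change was -3.17. Several of them belong to families of near-identical copies, so their single values are uncertain. In the ribosome biogenesis list 46 of 54 members fell (47 adjusted over the list alone), with a median of -2.70. Nop16, which helps assemble the large subunit, stood at 24.0, 29.1 and 22.8 FPKM in wild type and was listed at 0 in both alpha-amanitin libraries. Ebna1bp2 fell from 54.1 ± 17.8 to 1.60 ± 0.138 FPKM, and Rrp9, a protein of the U3 particle, from 48.2 ± 6.34 to 1.71 ± 0.652 FPKM. Of 76 cytosolic ribosomal protein genes 39 fell and none rose (46 fell adjusted over the list alone; median -1.84). Of 36 translation initiation factor genes 21 fell and 1 rose (21 and 1 adjusted over the list alone; median -1.22). Among them, Eif3c fell from 32.0 ± 3.91 to 1.17 ± 0.0744 FPKM and Eif6 from 109 ± 47.7 to 5.53 ± 4.00 FPKM (log2 change -4.80 without alpha-amanitin replicate 1 and -3.46 without replicate 2).

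Other lists of basic cell function held many genes that fell, but as lists none of the 6 that follow held with an estimated correlation (adjusted p = 0.0681 to 0.256). By fry, which does not compare a list with other genes, the adjusted p of these 6 was 3.23e-05 to 0.000799. Of 32 proteasome subunit genes 19 fell (24 adjusted over the list alone; median -1.90), such as Psmd12, from 24.1 ± 7.34 to 0.835 ± 0.567 FPKM. Of 49 splicing factor genes 28 fell (35 fell and 1 rose adjusted over the list alone; median -1.71), Srsf2 going from 163 ± 29.3 to 7.82 ± 4.67 FPKM and Srsf1 from 68.4 ± 12.3 to 6.78 ± 1.02 FPKM. Of 12 RNA polymerase II subunit genes 9 fell (9 adjusted over the list alone; median -1.71), Polr2d from 46.5 ± 9.15 to 1.41 ± 0.286 FPKM and Polr2b, which encodes a catalytic subunit, from 81.9 ± 19.4 to 9.09 ± 6.23 FPKM (log2 change -2.49 without alpha-amanitin replicate 1 and -3.84 without replicate 2). Of 28 heat shock and chaperonin genes 16 fell (18 fell and 1 rose adjusted over the list alone; median -1.58), among them the endoplasmic reticulum chaperone Hspa5, 9.27-fold. Of 25 pluripotency and early lineage transcription factor genes 13 fell (14 adjusted over the list alone; median -1.79): Gabpa went from 103 ± 22.5 to 1.38 ± 0.498 FPKM, Klf5 from 40.5 ± 12.1 to 0.290 ± 0.296 FPKM and Klf4 from 62.3 ± 2.60 to 6.84 ± 0.809 FPKM. Of 23 p53 target and apoptosis genes 9 fell (10 adjusted over the list alone; median -1.61), including the stress gene Sesn2, from 58.9 ± 7.10 to 0.158 ± 0.0453 FPKM.

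Of 80 oocyte and maternal effect genes 16 rose, 4 fell and 60 did not pass (16 and 4 adjusted over the list alone); 59 lay above 0 and the median change was 0.59 (adjusted p = 0.0681 with an estimated correlation). Zbed3, whose protein belongs to the subcortical maternal complex, was 3140 ± 132 FPKM in wild type and 8730 ± 678 FPKM with alpha-amanitin, 2.78-fold higher (a log2 difference of 0 under quantile normalization), and Bmp15, an oocyte growth factor, rose from 201 ± 40.5 to 475 ± 17 FPKM. Trim28, a co-repressor on the same list, fell from 103 ± 23 to 5.56 ± 6.18 FPKM; its log2 change was -5.54 without alpha-amanitin replicate 1 and -3.22 without replicate 2. The maternal mRNA decay list was split, with 3 genes higher and 6 lower of 22 (5 and 7 adjusted over the list alone): Cnot6l, a deadenylase subunit, rose from 58.8 ± 7.37 to 163 ± 5.67 FPKM and Cpeb2 fell from 14.8 ± 3.60 to 1.24 ± 0.195 FPKM. Large rises outside these lists included Dph6, an enzyme of diphthamide synthesis, from 23.9 ± 1.15 to 231 ± 52.6 FPKM, Cep41, a centrosomal protein gene, from 3.04 ± 3.08 to 33.9 ± 20.2 FPKM, and Ccdc42, at 0.258, 0.297 and 0 FPKM in wild type against 11.6 and 11.7. Osgin1 rose from 0.432 ± 0.262 FPKM to 6.84 and 27.1 FPKM, Ceacam2 from 1.87 ± 0.976 FPKM to 58.4 and 12.7 FPKM, and Nrxn3 from 0.918 ± 0.692 FPKM to 27.3 and 9.67 FPKM. Osgin1 and Cep41 also stood above wild type without alpha-amanitin, though neither was called there. Osgin1 was at 6.75 and 3.64 FPKM in mismatch controls and at 5.64 and 3.19 FPKM with the Kdm5a+b morpholinos. Cep41 was at 18.7 and 13.3 FPKM, and at 10.5 and 8.63 FPKM. In these injected libraries Nrxn3 ranged from 0.153 to 9.11 FPKM, Ceacam2 from 2.85 to 6.43, Dph6 from 30.9 to 50.6 and Ccdc42 from 0.158 to 1.18. The log2 change of Osgin1 was 4.31 without alpha-amanitin replicate 1 and 2.47 without replicate 2, that of Ceacam2 2.30 and 4.42, that of Nrxn3 2.54 and 3.95, and that of Cep41 3.87 and 2.61. The Nrxn3 call ended without wild-type replicate 1 (adjusted p = 0.0507), without alpha-amanitin replicate 1 (adjusted p = 0.14) and with no filter (adjusted p = 0.113). Sepp1 passed at an adjusted p of 0.0482, with 5.44 and 58.6 FPKM against 0, 0.628 and 1.04. Its call ended without wild-type replicate 1, 2 or 3, alpha-amanitin replicate 2, or mismatch control replicate 1 or 2 (adjusted p = 0.11, 0.0917, 0.0794, 0.349, 0.0521 and 0.0515). It also ended with a pseudocount of 0.1, no filter, TPM, the replicate block, eBayes without the trend, and array quality weights (adjusted p = 0.0794, 0.229, 0.0564, 0.0743, 0.0632 and 0.0785). Phf3, the largest rise by the rule, is not a measured change, because its 0 in all 3 wild-type libraries carries the status FAIL.

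By camera, 11 of the 20 lists passed: 10 lists that were relatively lower, led by ribosome biogenesis (adjusted p = 1.32e-14) and the 2-cell specific list (adjusted p = 6.24e-14), and the oocyte list, relatively higher (adjusted p = 6.18e-11). With an estimated correlation only the 2-cell specific and cytosolic ribosomal protein lists held (adjusted p = 0.0418 for each). Adjusted p with an estimated correlation was 0.0681 for the ribosome biogenesis, proteasome, splicing, oocyte and pluripotency lists. It was 0.0949 for polymerase II subunits and p53 targets, 0.221 for initiation factors and 0.256 for heat shock genes. Among the other 9 lists, Prdm9 and Ash2l fell and none rose of 16 genes for H3K4 methyltransferases and demethylases (2 adjusted over the list alone; Ash2l had an adjusted p of 0.0616 under quantile normalization), and 2 of the 3 Kdm5 genes fell (2 adjusted over the list alone). Of 38 replication-dependent histone genes 2 rose and 3 fell (0 and 2 adjusted over the list alone), with Hist1h2bm falling from 69.9 ± 28.2 to 7.17 ± 0.910 FPKM. Of 11 interferon-stimulated genes 5 fell (5 adjusted over the list alone), among them Irf7, from 8.38, 4.22 and 13.7 FPKM to 0 and 0.161. The H3K4, maternal decay and histone lists have medians below 0 (-0.25, -0.18 and -0.06) and a test direction above 0, since camera compares them with genes whose median is lower. Few markers of other cell types were tested: 3 cumulus genes, all lower (3 adjusted over the list alone), 3 sperm genes with 1 lower (1 adjusted over the list alone), 5 blood genes with none changed, and 4 oviduct genes with Epcam lower (1 adjusted over the list alone), which the embryo itself expresses.

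FPKM are relative, and the median change of all 13137 genes was -0.56. Quantile normalization, which forces the same distribution on every library, moved that median to 0.17 and gave 1716 genes higher and 1806 lower, 51.3% lower against 85.4%. The 11 lists kept their direction and their call under it, but the size of the change depended on the setting. Under quantile normalization the median was -1.12 for cytosolic ribosomal protein genes (-1.84 in the main fit) and -1.04 for proteasome genes (-1.9 in the main fit). For the 2-cell specific list it was -2.55 under quantile normalization and -5.33 with a pseudocount of 0.1 (-3.17 in the main fit). The count of rises was 362 without alpha-amanitin replicate 1 and 298 without replicate 2, against 566.

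**Figure D1:**
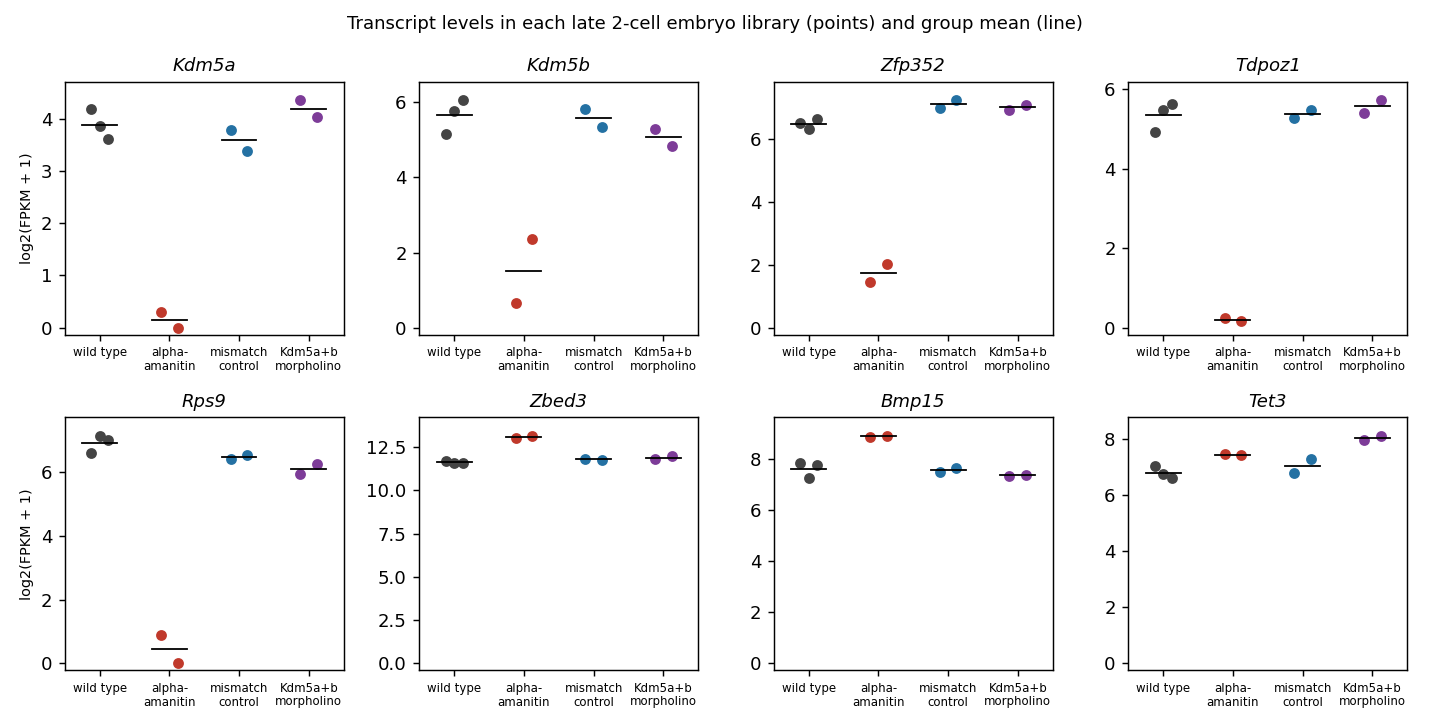
Level of 8 genes as log2(FPKM + 1) on the vertical axis, for each library (points) and the mean (line) of the 4 groups on the horizontal axis; axes start near 0 and differ between panels. Kdm5a, Kdm5b, Zfp352, Tdpoz1 and Rps9 are low in both alpha-amanitin libraries, Zbed3 and Bmp15 are high there (Zbed3 has a difference of 0 under quantile normalization), and Tet3 is highest in the 2 Kdm5a+b morpholino libraries.

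**Figure D2:**
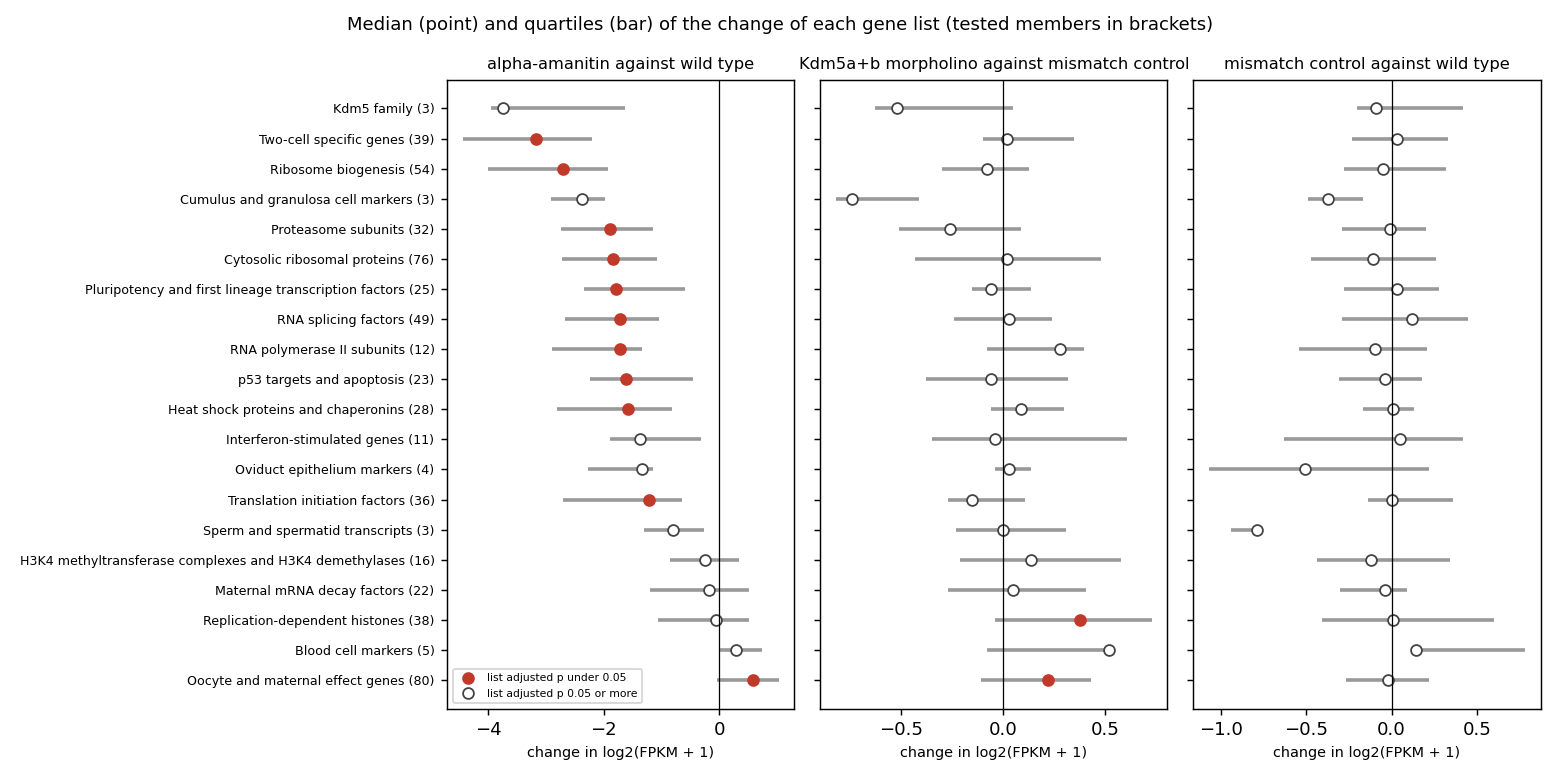
Change in log2(FPKM + 1) on the horizontal axis for the 20 gene lists, 1 panel per comparison, each with its own scale; points are medians, bars run from the lower to the upper quartile over the tested members, and red marks lists that passed camera at an adjusted p under 0.05. With alpha-amanitin 11 lists passed, of which 2 held with an estimated correlation (2-cell specific and cytosolic ribosomal protein genes); with the Kdm5a+b morpholinos the oocyte and histone lists passed, and neither held with an estimated correlation (adjusted p = 0.953 for each); in mismatch control against wild type none passed.

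Kdm5a+b morpholino against mismatch control asks which transcripts depend on the 2 demethylases by the late 2-cell stage, with injection matched. The transcriptomes were close: Kdm5a+b libraries correlated with control libraries across genes at r = 0.866 to 0.926, beside 0.902 between the Kdm5a+b replicates. Zfp352 was at 122 and 137 FPKM against 128 and 152 in the controls, and Rps9 was at 60.5 and 76.4 FPKM against 84.1 and 91.8. No gene of 13137 passed limma's test at an adjusted p under 0.05, and 414 had an unadjusted p under 0.05 (243 higher, 171 lower), where 657 would come from chance with no effect. That count was 729 without mismatch control replicate 1, 246 without mismatch control replicate 2 and 237 without Kdm5a+b replicate 2. With only the libraries of the 2 groups compared, 574 genes had an unadjusted limma p under 0.05, and with array quality weights 650. The 4 groups share 1 estimate of the spread, so a count under 657 is no evidence of absent effects. The smallest adjusted p in the main fit was 0.28. It belonged to Gyg, which encodes the protein primer of glycogen synthesis, at 248 and 261 FPKM against 54.6 and 51.3 FPKM, a log2 difference of 2.24 (SE 0.32), and to Glrx5, a mitochondrial glutaredoxin of iron-sulfur cluster assembly, at 40.7 and 56.6 FPKM against 10.5 and 6.67 FPKM, 2.38 (SE 0.36). Glrx5 was at 20.2, 18.9 and 21.8 FPKM in wild type, above the mismatch controls, and its adjusted p was 0.0457 with no filter. Gyg and Glrx5 were chosen after their values were seen. Gyg lies on mm10 chromosome 3, 20122084 to 20155317, and Glrx5 on chromosome 12, 105032689 to 105040910. With wild-type libraries as the reference, Gyg alone passed (log2 difference 2.57, SE 0.29, adjusted p = 0.0468; 55.6, 28.5 and 46.6 FPKM in wild type). Gyg also stood above wild type with alpha-amanitin, at 117 and 157 FPKM, so a higher level is not particular to the Kdm5a+b group.

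In the gene lists no single member passed, over all genes or adjusted over the list alone. By camera 2 of 20 lists passed, both relatively higher, and neither call held with an estimated correlation (adjusted p = 0.953 for each). The 80 oocyte and maternal effect genes had a median change of 0.22, with 52 above 0 (camera adjusted p = 0.0132). The median was 0.11 without mismatch control replicate 2 and 0.38 without mismatch control replicate 1. The members of the oocyte list with the smallest p were Tet3, Tcl1b4 and Tcl1b3. Tet3, a dioxygenase that acts on methylated DNA of the zygote, was at 251 and 279 FPKM against 109 and 154. Tcl1b4 was at 112 and 95.7 FPKM against 81.2 and 45.8, and Tcl1b3 at 203 and 146 FPKM against 122 and 100. In wild type Tet3 was at 132, 108 and 96.1 FPKM and Tcl1b3 at 104, 90.3 and 122 FPKM. Tcl1b4 was at 88.6, 87.9 and 92.9 FPKM in wild type, above both mismatch controls. The 38 replication-dependent histone genes had a median of 0.38, with 27 above 0 (adjusted p = 0.0228); Hist1h2bl was at 21.6 and 30.8 FPKM against 10.4 and 7.29, and Hist1h3g at 8.54 and 18.5 FPKM against 1.77 and 5.51. Wild-type levels were 12.6, 11.3 and 29.9 FPKM for Hist1h2bl, above both mismatch controls, and 8.51, 3.28 and 6.01 FPKM for Hist1h3g. Histone genes have near-identical copies, so their single values are uncertain. By fry, which tests a list against no change and not against other genes, the adjusted p was 0.906 for each. The histone call also ended with a pseudocount of 0.1 (adjusted p = 0.0503) and with no filter (adjusted p = 0.162), and the oocyte call under quantile normalization (adjusted p = 0.0772). The oocyte call ended without mismatch control replicate 2 (adjusted p = 0.326), the histone call without mismatch control replicate 1 (adjusted p = 0.232), and both without Kdm5a+b replicate 1 (adjusted p = 0.521 for each). The 39 tested 2-cell specific genes had a median of 0.02, the 54 ribosome biogenesis genes -0.08, the 76 cytosolic ribosomal protein genes 0.02 and the 32 proteasome genes -0.26 (adjusted p = 0.742, 0.742, 0.947 and 0.202). Adjusted p was 0.434 or more for the other 14 lists.

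The next question was whether genes that fall without new transcription differ with the Kdm5a+b morpholinos. The 3299 genes lower under alpha-amanitin had a median change of -0.04 with the Kdm5a+b morpholinos, quartiles -0.31 and 0.25, and 52.9% of them lay below 0 (camera p = 0.272; p = 0.608 with an estimated correlation). Their overlap with genes lower in the Kdm5a+b group was 0, since none was called there. Across genes, which are not independent replicates, Spearman's rho between the 2 sets of log2 changes was 0.0721 and Pearson's r was 0.0607; rho was 0.0264 without mismatch control replicate 1 and 0.114 without replicate 2. The comparisons share no library. On simulated data the Kdm5a+b comparison recovered 36.4% of 4-fold but 1.79% of 2-fold changes, so differences near 2-fold were mostly not detectable here.

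**Figure D3:**
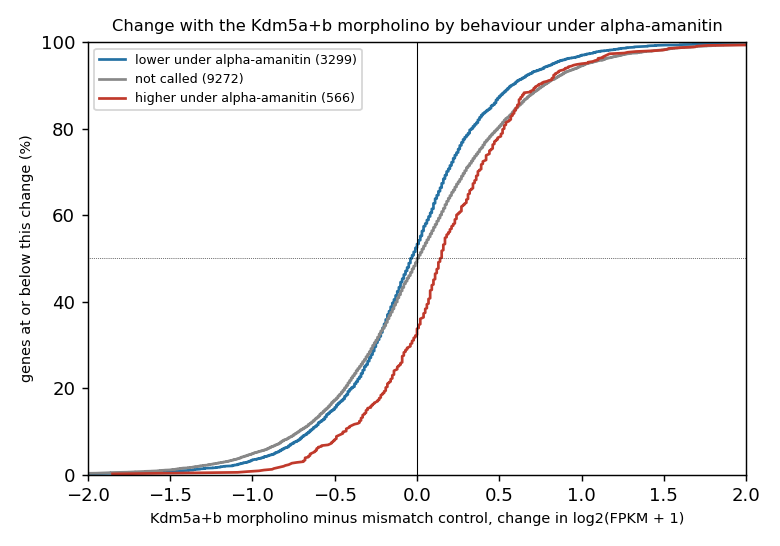
Cumulative share of genes in percent (vertical axis) by their log2 difference between Kdm5a+b morpholino and mismatch control libraries (horizontal axis), for 3299 genes lower, 566 genes higher and 9272 genes not called under alpha-amanitin. The curve of the genes lower under alpha-amanitin crosses 50% near its median of -0.04, and that of the genes higher under alpha-amanitin at 0.14.

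Mismatch control against wild type measures the effect of injection and of a control oligomer. Zfp352 was at 128 and 152 FPKM against 92.0, 79.3 and 99.4 in wild type (log2 difference 0.63, SE 0.26, adjusted p = 0.999), and Zbed3 at 3550 and 3500 FPKM against 3280, 3020 and 3100. No gene passed limma's test, and the smallest adjusted p was 0.709. An unadjusted p under 0.05 was found for 616 genes, with 334 higher and 282 lower, against 657 by chance. With only the libraries of the 2 groups it was found for 508, and with array quality weights for 633. Here too the spread is shared by the 4 groups, so a count under 657 is no evidence of absent effects. The unadjusted count was 370 without mismatch control replicate 2, 742 without mismatch control replicate 1, 717 without wild-type replicate 1 and 833 without wild-type replicate 2. None of the 20 gene lists passed, and no list member passed over all genes or adjusted over the list alone. The list with the smallest p was the 3 sperm and spermatid transcripts, with a median of -0.79 (adjusted p = 0.602). The oocyte list had a median of -0.02 and the 2-cell specific list of 0.03 (adjusted p = 0.916 for each). Hdhd2, chosen after its values were seen, was at 4.74 and 8.72 FPKM against 0.119, 0.00563 and 0.509, and at 0.109 and 0.722 FPKM in the other injected group, Kdm5a+b morpholino. The control libraries were measured more deeply than the wild-type ones (relative depth 2.26 and 1.59 against 1.00, 0.87 and 0.88), and injection cannot be separated from that difference.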

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

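The count of genes changed under alpha-amanitin stayed between 2886 and 4406 in the settings other than leave-one-out (3865 as reported) and between 2676 and 3657 without 1 library. In each of these settings most called genes were lower, by the least under quantile normalization (51.3%). The counts of 0 for Kdm5a+b morpholino against mismatch control and mismatch control against wild type became 27 and 11 with no filter on low values; the cause was not tested. Against wild-type libraries, and against wild-type and control libraries together, 1 gene was called in the Kdm5a+b group, Gyg in both. Without 1 library, these counts ranged from 0 to 3 in each comparison. In the other settings they stayed 0. Of the gene lists under alpha-amanitin, 2 held with an estimated correlation, and 11 to 12 passed without 1 library. For the Kdm5a+b comparison, 1 list passed with a pseudocount of 0.1, 1 with quantile normalization, 0 with an estimated correlation, 0 with fry, and 0 to 2 without 1 library; the cause was not tested. The overlap of genes lower in both comparisons was 49 at an unadjusted p under 0.05 on the Kdm5a+b side, chosen after seeing the data, against 42.9 for independent lists (Fisher's exact test, two-sided p = 0.287). Genes lower under alpha-amanitin and higher in the Kdm5a+b group numbered 43, against 61 (Fisher's exact test, p = 0.00703). The reverse held for 2 genes, against 7.4 (Fisher's exact test, p = 0.0359). These p-values treat genes as independent. Of the genes named in a comparison, 57 stayed on one side of the threshold in the settings run gene by gene (at most 23, without the changed references, under which Gyg gained a call) and 12 did not: 25 values lost a call and 5 gained one, with the same direction. Zbed3 had a difference of 0 under quantile normalization, which gives equal values to equal ranks, and its adjusted p was 0.384 with no filter. Without 1 library the log2 difference of Kdm5a+b from control embryos ranged from 0.41 to 0.81 for Kdm5a and from -0.75 to -0.28 for Kdm5b, and the median of the genes lower under alpha-amanitin from -0.12 to 0.06. Replicate numbers recur in every group, but deviations of libraries with the same number correlated at -0.05 to 0.04 across genes, so the numbers were not read as pairs. With a replicate block 3115 genes were called under alpha-amanitin (3687 with wild-type replicate 3 in the level of replicate 2) and 0 in each of the other 2 comparisons. Leaving out mitochondrial and ribosomal RNA genes was not run, because the 2 lists of such genes, matched by symbol, found none. Other rows, such as Yam1, could still collect ribosomal RNA reads, which was not tested. Where a library is left out of a pair, the lone library is assumed to vary like the other groups. Read depth is unknown, so its limit could not be set beyond the widths of the FPKM bounds.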

Other observations

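The tests of single libraries, failed estimates, a common factor and spiked-in RNA were chosen after the results were seen, as was the set of genes that rose under alpha-amanitin. Of the 10 most abundant transcripts in wild type, 5 were higher under alpha-amanitin, 2 lower and 3 not called (limma); those named here were chosen after their values were seen. Yam1 (mm10 chromosome 17, 39846958 to 39848788), the row with the highest FPKM, was at 12500 ± 4850 FPKM (SD, n = 3) in wild type. With alpha-amanitin it was at 10300 ± 2620 FPKM (SD, n = 2), a log2 difference of -0.21 (SE 0.31, limma adjusted p = 0.637). Whether its reads come from ribosomal RNA was not tested, so its level is not read as that of an mRNA. The oocyte transcript Omt2a was at 1270 ± 124 and 1150 ± 18.6 FPKM (-0.15, SE 0.14, adjusted p = 0.47), and its neighbour Omt2b fell from 1150 ± 115 to 679 ± 15 FPKM (adjusted p = 0.00372, limma; 0.0526 without alpha-amanitin replicate 1, 0.227 with no filter and 0.112 with eBayes without the trend). Without wild-type replicate 2, Yam1 passed (-0.59, adjusted p = 0.0444). Rbm38, an RNA-binding protein gene, rose from 1170 ± 308 to 2150 ± 167 FPKM (adjusted p = 0.00628, limma; 0.0736 without alpha-amanitin replicate 1, 0.278 under quantile normalization and with no filter, and 0.0872 with eBayes without the trend). By biotype, 2840 of 11297 protein-coding genes (25.1%) and 274 of 901 processed pseudogenes (30.4%) were lower, and 38 of 218 long intergenic non-coding RNA genes (17.4%).

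As a set, genes that rose under alpha-amanitin, in libraries that the Kdm5a+b comparison does not use, were shifted upward in the Kdm5a+b group relative to other genes, though no single gene was called there. The median of the 566 genes was 0.14, 66.8% lay above 0 and 33.2% below (camera p = 7.75e-05; p = 0.0352 with an estimated correlation), and each of the 4 pairs of libraries gave 0.11 to 0.18; at an unadjusted p under 0.05, 27 of them were higher, against 10.5 for independent lists (Fisher's exact test, two-sided p = 6.16e-06). Fisher's test treats genes as independent. The set's median in the shallower minus the deeper library of an injected group was -0.02 and 0. These medians and those of the 4 pairs are of the set alone, not relative to other genes. The median of all tested genes also moved between libraries. In the Kdm5a+b comparison it was 0.08 without mismatch control replicate 1 and -0.04 without mismatch control replicate 2. Depth as a cause of the relative shift is therefore not decided. The set's median lay above 100% of 10000 random lists matched on mean level over all 9 libraries (highest 0.1). Those include the alpha-amanitin libraries, where the set is high by choice, and random lists treat genes as independent. A trend with expression level in the libraries compared is therefore not decided. A difference between single libraries cannot be told apart, because 2 against 2 libraries give no share under 0.333. An effect of the Kdm5a+b morpholinos stays open, as untested.

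The same 566 genes had a median of 0.28 in mismatch control against wild type, with 79.5% above 0. The 3299 genes lower under alpha-amanitin had a median of -0.1 there, with 58.9% below 0. That comparison shares wild-type libraries with the one that chose the genes. For genes that rose, 20 simulated draws of unchanged control groups gave medians of 0.07 to 0.15, with 61.8% above 0 on average. The draws had noise independent between genes, so their range leaves out shifts that many genes of a library share. Such a shift and an effect of injection cannot be told apart here.

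The calls gained when 1 library was left out of the morpholino comparisons were mostly failed estimates. There were 11 such calls at 7 genes, and 90.9% sat at a gene with the status FAIL in a compared library. Ubap2, named after its values were seen, was listed at 0 in mismatch control replicate 1 and stood at 92.1 FPKM in replicate 2. With genes of any other status than OK set aside, at most 0 calls were left for Kdm5a+b against control and 1 for control against wild type. No biological explanation was tested.

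The rises under alpha-amanitin may come in part from relative units: with less new mRNA, each stable transcript takes a larger share. The median rise of the 566 genes was 1.46, with quartiles 1.09 and 1.85, and 108 rose more than 4-fold. By their limma SE, 6 of them differed from that median at an adjusted p under 0.05 (2 above, 4 below). That count lies between the bounds set for and against 1 common factor. It cannot decide, because the genes were chosen as called higher and a rise can fail to differ through a wide SE alone. The test at first counted the rises above the median alone; those 2 would have met the bound for a common factor, and the count was widened to both directions after that was seen. The size of a common shift and a change in the amount of each transcript cannot be told apart, as 0 rows of spiked-in RNA are in the files. Slower decay of maternal transcripts when transcription is blocked stays open, as untested.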
